A study of Mus musculus with 9 samples.

How the data were processed

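Expression was measured on 9 Affymetrix Mouse Gene 1.0 ST arrays, which read whole transcripts with probes along each gene. Per the labels, the RNA came from cultures of the subventricular zone of electroporated mouse brains. Cells were passaged in a serum-free medium with epidermal and fibroblast growth factors and sorted for high GFP. The arrays form 3 groups of 3: glioma lines labelled with a mutant Erbb2 transgene, glioma lines labelled with a mutant Hras transgene, and neural stem and progenitor cells (NSC) that carried reporter genes alone. Arrays are named by group and by the number in their title. The NSC arrays differ in reporter: a membrane EGFP in NSC 1, an EGFP-tagged histone in NSC 2, and a blue fluorescent protein without EGFP in NSC 3. The description of NSC 3 names a sort for the blue protein, while its source name, like the others, says EGFP purified. NSC 3 is also the only array from mice of a C57/Bl6 strain with a floxed Dnm2 gene, the others being CD1. The description of the array titled as Hras line 3 carries the number 4 in place of 3, and the title was followed. The descriptions also open with a number of unstated meaning, 1 to 3 for the tumour arrays, 4 for NSC 1 and 2 and 5 for NSC 3, which was not used. The labels do not say that the 3 lines of a group came from separate animals, so p-values measure only the spread between these cultures, part of which can be technical.

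Both deposited tables were used. The gene table holds log2 values for 20715 rows, deposited by the authors with a gene symbol each. The value table holds linear intensity values for 35512 probe sets, deposited without gene names, and 1 of its rows is empty. For 20171 genes the log2 value equalled the log2 of 1 probe set's intensity on all arrays within a tolerance of 1e-04, and 519 genes equalled none. The background correction, the normalization, the summary of probes and the choice of a probe set per gene are not given in the sources used here. In the gene table, 25 rows have a number in place of a symbol, as spreadsheets make of some gene names, and were left out. The tests ran on the other 20690 genes, of which 19258 carry a current RefSeq symbol of the mouse reference table, and no symbol occurs more than 1 time. All 9 value columns of each table were matched to a sample, leaving 0 unmapped.

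The arrays were not on an identical scale. The median log2 value over genes was 6.68, 6.56 and 6.73 in Erbb2 1, 2 and 3, 7.06, 7.19 and 6.98 in Hras 1, 2 and 3, and 6.81, 6.56 and 6.69 in NSC 1, 2 and 3. The median intensity over probe sets was 60.7, 59.1 and 58.7 in the Erbb2 arrays, 75.3, 94.6 and 80.6 in the Hras arrays, and 85.4, 61.8 and 79.5 in the NSC arrays. Over all genes the median log2 change was 0.16 for Hras against NSC, -0.14 for Erbb2 against NSC, 0.29 for Hras against Erbb2 and 0.01 for the mean of both tumour groups against NSC. That median is the reference for small changes of gene lists in the first 3 comparisons. No detection call per gene was used, and the precision rests on the number of arrays.

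The deposited log2 values were tested with limma 3.58.1 in R 4.3.3. All 9 arrays entered a single fit of group means (lmFit and eBayes), so that the groups share an estimate of the spread, with 6 residual and 3.12 prior degrees of freedom. Contrasts were Hras minus NSC, Erbb2 minus NSC, Hras minus Erbb2, and the mean of the 2 tumour groups minus NSC. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Gene lists were tested with limma's competitive set test camera at a preset inter-gene correlation of 0.01, adjusted over the 32 lists. The lists cover Ets factors, signalling pathways, cell types and states of the brain, stress and metabolism, and the markers of other cell types that a culture could hold. They name 830 members, of which 822 were matched to the gene table, in part through older symbols. The same lists were tested with a correlation estimated from the data and with the rotation test fry, in its directional and its mixed form. The mixed form asks whether members changed in either direction. The contrasts, lists, tests and most alternatives were fixed before the data were examined.

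Genes named in the text follow a rule fixed in advance. It takes the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap, passing over predicted genes, clones and receptor families. For a list that the text describes it takes up to 4 members with the smallest adjusted p, or, where no member was called, up to 2 with the largest change, given as values. It always takes the genes of both transgenes, Etv1, Etv4, Etv5, Dnm2 and the sex-linked genes. The rule was written for the pairwise comparisons. Its use for the mean of both tumour groups, and the list tests of that contrast, were chosen after the pairwise counts had been seen. Genes that lie outside the rule are marked as chosen after their values were seen. Some genes that the rule takes are not reported here.

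The procedure was checked on simulated data with the arrays' own spread and 200 changed genes among 20690. For Hras minus NSC it recovered 8.28% of genes changed by 1 log2 unit, 76.1% at 2 units and 97.3% at 4 units, with 4.66% false calls. For the mean of both tumour groups minus NSC it recovered 21%, 85% and 98.6%, with 5.71% false calls. A list of genes shifted by 1 log2 unit was called by camera in 20 of 20 simulations of Hras minus NSC, and 2 of 620 unshifted lists were called. The simulated genes varied independently of each other, and the simulated arrays had no structure besides the groups. In the data the estimated correlation within a list ran from 0.04 (ErbB receptors and ligands) to 0.75 (replication-dependent histones). A split of the real arrays across the groups, with Erbb2 1, Hras 1 and Erbb2 2 set against the rest, called 204 genes. The simulation therefore does not give the rate of false gene or list calls in these data. Alternatives were the values of the other deposited table, quantile normalization, centring each array on its median, a filter on dim genes that left 16639 genes with a group mean above 5.31, fits of the compared groups alone, a trended robust variance, array weights, other thresholds, limma's treat test, the title number as a block, and the removal of each array in turn.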

Results

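Gene expression was compared between glioma lines made by electroporating a mutant Hras or a mutant Erbb2 transgene into neural stem cells of the mouse brain, and NSC cultures that received reporters alone. There were 3 arrays per group. Erbb2 encodes a receptor tyrosine kinase and Hras a GTPase downstream of it, and the title of the series sets Ets transcription factors in gliomas of the Ras pathway as its subject. The comparisons ask which genes separate the tumour lines from NSC, and whether the lines of the 2 oncogenes differ.

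Neither transgene's own gene was called between the groups. Hras, listed under its older symbol Hras1, had a log2 level of 9.44 ± 0.13 (SD, n = 3) in the lines labelled Hras, 9.0 ± 0.21 (SD, n = 3) in those labelled Erbb2 and 9.27 ± 0.47 (SD, n = 3) in NSC. Each Hras line (9.29 to 9.53) lay above each Erbb2 line (8.82 to 9.24), and the NSC arrays (8.96 to 9.81) overlapped both (Hras against Erbb2 lines, limma adjusted p = 0.443). The Hras and Erbb2 lines lay apart in either direction for 27.7% of all genes, where chance gives 10%. Erbb2 had 8.14 ± 1.09 (SD, n = 3) in the lines labelled Erbb2, 7.93 ± 0.61 (SD, n = 3) in those labelled Hras and 7.40 ± 0.29 (SD, n = 3) in NSC, with Erbb2 line 2 at 7.0. Whether the probes of these genes detect the transgenes is not known from the files, so these values neither bear out a label nor speak against it. In what follows, Hras lines and Erbb2 lines are the lines so labelled.

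The PEA3 Ets factors, which are transcribed downstream of ERK signalling, were expressed in all groups. Etv1 had log2 levels of 11.12 ± 0.33 (SD, n = 3) in Erbb2 lines, 10.93 ± 0.64 (SD, n = 3) in Hras lines and 10.41 ± 0.66 (SD, n = 3) in NSC. Etv4 had 9.34 ± 0.61, 9.15 ± 0.30 and 8.44 ± 0.69, and Etv5 had 10.68 ± 0.62, 10.30 ± 0.56 and 10.19 ± 1.02 in the same order (SD, n = 3 each). In limma's test none of the 3 was called in any comparison, with adjusted p between 0.545 and 0.574 for Etv4 and Etv1 and 0.713 for Etv5 in Erbb2 lines against NSC, and 0.547, 0.692 and 0.961 for Etv4, Etv1 and Etv5 in Hras lines against NSC. Etv5 changed the sign of its difference between Hras lines and NSC, from 0.11 to -0.11 after quantile normalization, to -0.19 without Hras 2 and to -0.48 without NSC 1, and between Erbb2 lines and NSC from 0.49 to -0.09 without NSC 1. As a list of 3 genes the PEA3 factors were shifted up in Erbb2 lines against NSC, with a median log2 change of 0.72 (camera adjusted p = 0.0323), and 0 of 3 were called over all genes or adjusted over the list alone. The adjusted p = 0.709 with an estimated correlation, and the call was also lost after quantile normalization (adjusted p = 0.126), without dim genes (0.0655) and without Erbb2 1 (0.0558), Erbb2 3 (0.0822) or NSC 1 (0.366). The median was 0.34 without NSC 1. In Hras lines against NSC the list had a median of 0.52 and was not called (camera adjusted p = 0.579).

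**Figure D1:**
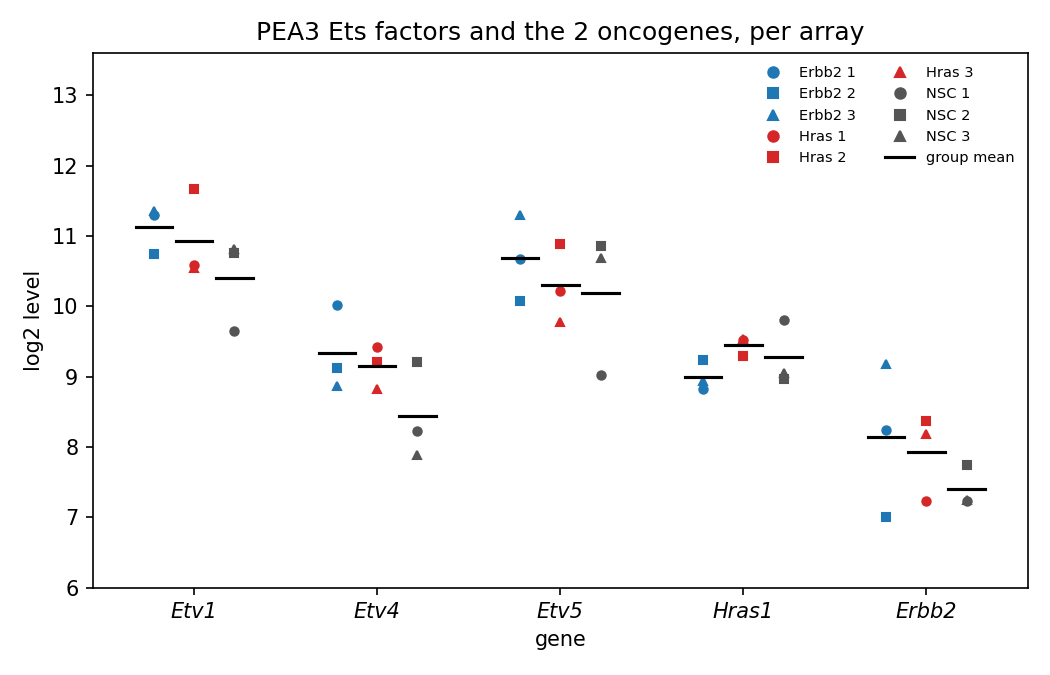
Log2 level (vertical axis) of Etv1, Etv4, Etv5, Hras1 and Erbb2 on each array, with symbols for the array number, colours for the group and a bar for the mean of 3 arrays. The groups overlap for Etv1, Etv4, Etv5 and Erbb2, and the 3 Hras arrays lie between 9.29 and 9.53 for Hras1, within the range of the NSC arrays, 8.96 to 9.81.

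Set against NSC as the mean of both tumour groups, the lines expressed more Pdgfra, Syt4 and Itga8 and less Rfx4, Slc6a11, Grm3 and Egfr. Pdgfra, the PDGF receptor of oligodendrocyte precursors, rose by 4.92, to 10.46 ± 1.08 (SD, n = 6) against 5.53 ± 0.33 (SD, n = 3) on the log2 scale (SE 0.59, limma adjusted p = 0.0246). The vesicle protein Syt4 rose by 4.77, the integrin chain Itga8 by 4.68 and the integrin chain Itga1 by 2.87. Rises of 2.84 to 3.18 were measured for Pcolce, which aids collagen maturation, the laminin chain Lama4, the apolipoprotein Apod, the ceramide synthase Cers4, the taurine transporter Slc6a6 and the desaturase family member Fads3. Rfx4, a transcription factor of the neural tube, fell by 4.56 (SE 0.51, adjusted p = 0.0246), from 10.25 ± 0.82 (SD, n = 3) to 5.68 ± 0.77 (SD, n = 6).

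The GABA transporter Slc6a11 fell by 4.32, the glutamate receptor Grm3 by 3.88 and the EGF receptor Egfr by 3.76. Nrn1, Plcd4, Car2, Lpo, Fgfr3 and Apln fell, with changes of -3.51, -3.43, -3.16, -2.95, -2.51 and -2.38. Lpo and Itga8 had the smallest adjusted p, 0.0175 each. For Pdgfra and Itga8 1 NSC array each, and for Rfx4, Grm3, Egfr, Nrn1 and Plcd4 1 or more tumour arrays, lay below the dim limit of 5.31 and are not shown to be above background, so the sizes of these changes rest in part on such levels. In all, 73 of 20690 genes were called, 53 higher and 20 lower in the tumour lines, with a median absolute change of 2.18 log2 units, and 2078 genes had an unadjusted p under 0.05 where chance gives 1034.5.

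The calls lay close to the threshold, and 0 genes passed an adjusted p under 0.01. Without a given array the count was 0 (NSC 2), 1 (Erbb2 1), 5 (Hras 2), 6 (Hras 1), 20 (NSC 1), 21 (NSC 3) or 35 (Hras 3), and 53 (Erbb2 2) or 70 (Erbb2 3), so each of the genes named above lost its call without at least NSC 2. Quantile normalization left 12 calls, 2 higher and 10 lower, and centring each array left 23, 8 higher and 15 lower. All 73 kept their direction after quantile normalization, with a median absolute change of 2.22, which changes this large, called in these same data, made likely.

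**Figure D2:**
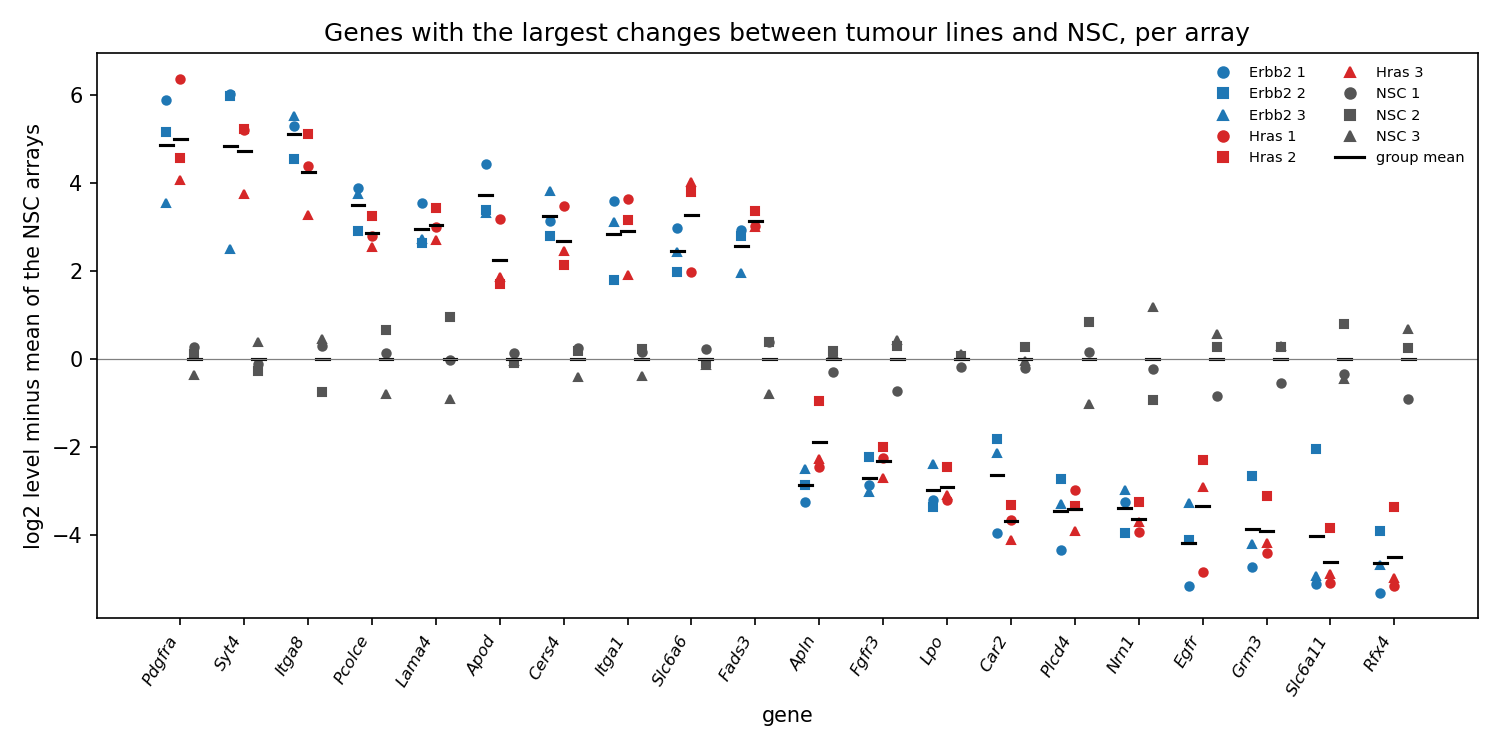
Log2 level minus the mean of the 3 NSC arrays (vertical axis) for the 10 genes with the largest rises and the 10 with the largest falls in the mean of both tumour groups against NSC, with symbols for the array number, colours for the group and a bar for each group's mean. The mean change runs from 4.92 for Pdgfra to -4.56 for Rfx4, and for each gene all tumour arrays lie on the same side of all NSC arrays, as the choice of genes required.

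Of the 73 genes, 18 belong to a list fixed in advance. Among 19 integrins, Itga8, Itga1 and Itga4 rose, the last by 2.76, and 0 fell, while adjusted over the list alone 5 rose and 1 fell. Among 23 oligodendrocyte precursor genes, Pdgfra and Ppfibp1 rose, the latter by 2.62, and the same number passed when adjusted over the list alone. The proteoglycan Cspg4, a classical marker of these cells, differed by 2.16 (SE 0.69, adjusted p = 0.295). Among 37 matrix proteases and inhibitors, the aggrecan-cleaving Adamts5 rose by 2.83 and the plasminogen activator Plat fell by 1.40, both also when adjusted over the list alone. Of 28 genes of neural stem cells and radial glia only Egfr fell over all genes, and 3 fell when adjusted over the list alone. Lfng, a modifier of Notch receptors, differed by -2.89 (adjusted p = 0.0929) and Sox1 by -0.75 (adjusted p = 0.147). Of 20 astrocyte genes Fgfr3 fell, and 3 fell when adjusted over the list alone, with Aldh1l1 at -3.96 (adjusted p = 0.135) and Mlc1 at -3.58 (adjusted p = 0.164).

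Single members were called in further lists. Ifi35 rose by 2.63 among 38 interferon response genes, Atf3 by 1.80 and Edem1, which acts in the disposal of misfolded proteins, by 1.17 among 30 genes of the ATF4 and unfolded protein response, Cxcl14 by 1.78 among 34 cytokines and chemokines, and the mesenchymal transcription factor Prrx1 by 2.82 among 21 pericyte and fibroblast genes. Trp53inp1 fell by 1.83 among 31 p53 targets and CDK inhibitors, Bmpr1b, a receptor of bone morphogenetic proteins, by 2.27 among 31 genes of the TGF-beta and BMP pathway, and the homeobox gene Otx2 by 2.25, from 7.15 ± 0.94 (SD, n = 3) to 4.90 ± 0.23 (SD, n = 6). The level of Otx2 in the tumour lines, like that of Adamts5 in NSC (5.13), lay below the dim limit of 5.31 and is not shown to be above background. These single calls were lost without NSC 2 like all others.

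Several lists moved together against NSC. In the mean of both tumour groups, 41 of 46 cell cycle genes had a positive change, with a median of 0.73 (camera adjusted p = 9.38e-13), and 12 passed when adjusted over the list alone against 0 over all genes. The adjusted p = 0.447 with an estimated correlation. Genes of the ATF4 and unfolded protein response had a median of 0.81 (camera adjusted p = 2.38e-10), 2 rose over all genes and 13 when adjusted over the list alone (adjusted p = 0.447 with an estimated correlation). Interferon response genes had a median of 0.92 (camera adjusted p = 8.08e-06), with 1 rise over all genes and 2 over the list alone (adjusted p = 0.564 with an estimated correlation). Sterol synthesis genes had a median of 0.52 (camera adjusted p = 0.000961), with 22 of 25 positive and 0 called either way. Their list had an adjusted p = 0.564 with an estimated correlation. These 4 lists kept their camera call under each of the 13 scalings, filters, blocks and removals of an array that were run. The cell cycle median was 1.10 without NSC 1 and 0.49 without NSC 2, and the sterol median 0.32 without NSC 2. The cell cycle list's mean against NSC was 0.29 to 0.38 in the Erbb2 lines, within the range of the NSC arrays (-0.51 to 0.74). The interferon list's mean against NSC was -0.45 in Erbb2 1, -0.31 in Erbb2 2 and 0.09 in Hras 1, and 1.45, 1.99 and 3.18 in Hras 2, Erbb2 3 and Hras 3.

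The astrocyte list (median -0.55, camera adjusted p = 0.000213) and the list of neural stem cells and radial glia (median -0.47, camera adjusted p = 8.17e-05) were shifted down. Both had an adjusted p = 0.447 with an estimated correlation, and both calls were lost without NSC 2, at adjusted p = 0.147 and 0.0595. The oligodendrocyte precursor list was shifted up (median 0.77, camera adjusted p = 0.00776, adjusted p = 0.659 with an estimated correlation), a call lost without Hras 1 (0.128) or NSC 1 (0.446). The astrocyte median was -1.27 without NSC 1 and -0.35 without NSC 2, and the oligodendrocyte precursor median 0.48 without Hras 1 and 1.19 without Hras 3. In Erbb2 lines alone against NSC the astrocyte list was not called (camera adjusted p = 0.108). Its mean against NSC was -1.57 in Erbb2 1 and -1.31, -0.84 and -1.16 in Hras 1, 2 and 3. In Erbb2 2 and 3 it was -0.45 and -0.39, above NSC 1 at -0.50. The array NSC 1 had the lowest weight of the 9, 0.288, in limma's array weights. In all, 16 of 32 lists were called in this contrast, 11 up and 5 down, and 0 with an estimated correlation or with the directional form of fry.

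**Figure D3:**
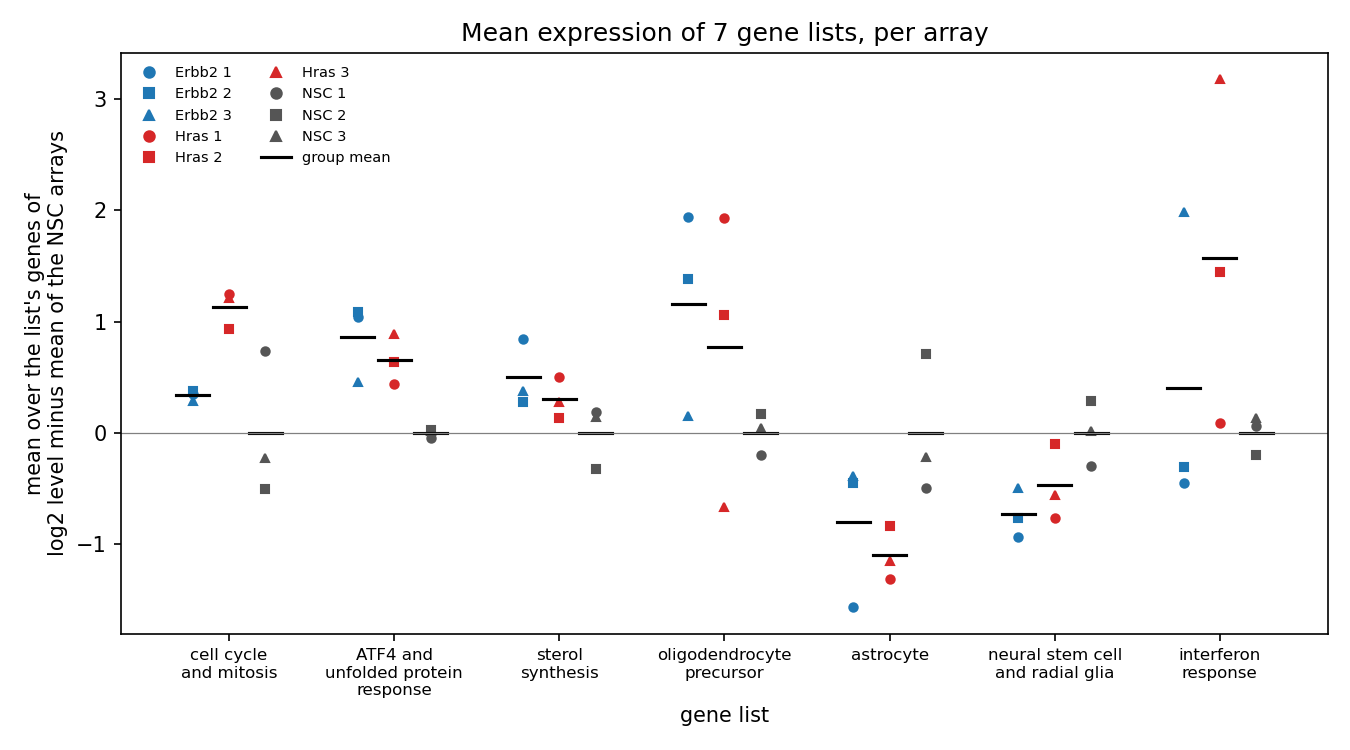
Mean over each list's genes of the log2 level minus the mean of the NSC arrays (vertical axis) for 7 gene lists on each array, with symbols for the array number, colours for the group and a bar for each group's mean. The 3 Hras arrays lie between 0.93 and 1.25 for the cell cycle list, above the NSC arrays at -0.51 to 0.74. The 3 Erbb2 arrays, at 0.29 to 0.38, lie within the NSC range for that list. The interferon response list ranges from -0.45 in Erbb2 1 to 3.18 in Hras 3.

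In the Hras lines, cell cycle genes were higher and astrocyte genes lower than in NSC as lists. Of 46 cell cycle genes 45 had a positive change, with a median of 1.17 (camera adjusted p = 1.03e-15), and 25 passed when adjusted over the list alone against 0 over all genes. The adjusted p = 0.32 with an estimated correlation. The kinetochore motor Cenpe was at 8.50 ± 0.59 against 6.20 ± 0.30 (SD, n = 3 each, change 2.31, limma adjusted p = 0.083), and the phosphatase Cdc25c differed by 2.01 (adjusted p = 0.164). Of 20 astrocyte genes 15 had a negative change, with a median of -1.14 (camera adjusted p = 1.18e-07), and 3 fell when adjusted over the list alone (adjusted p = 0.314 with an estimated correlation). Aldh1l1, a folate enzyme used as an astrocyte marker, differed by -4.13 and the membrane protein Mlc1 by -4.14 (adjusted p = 0.162 each). The astrocyte median was -0.74 without Hras 3 and -0.51 without NSC 2.

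The list of neural stem cells and radial glia was also shifted down in the Hras lines, with a median of -0.21, or -0.37 relative to all genes, and 2 falls over the list alone (camera adjusted p = 1.93e-05, adjusted p = 0.32 with an estimated correlation). Egfr differed by -3.35 (adjusted p = 0.12) and Lfng by -2.63 (adjusted p = 0.164). The ATF4 and unfolded protein response list was shifted up, with a median of 0.70 and 5 rises over the list alone (camera adjusted p = 7.26e-05, adjusted p = 0.562 with an estimated correlation). Its member Atf3 differed by 1.67 (adjusted p = 0.102). The list of 31 p53 targets and CDK inhibitors was shifted down with members on both sides, 3 rising and 4 falling when adjusted over the list alone (median -0.28, or -0.44 relative to all genes, camera adjusted p = 0.000435, adjusted p = 0.32 with an estimated correlation). Trp53inp1 differed by -1.85 (adjusted p = 0.0733) and Gadd45b by 1.69 (adjusted p = 0.157), and the call was lost when arrays were centred (adjusted p = 0.2), with a median of -0.67 beside -0.23 for all genes. The median of the stem cell and radial glia list was -0.016 without Hras 1, -0.49 without Hras 2, -0.068 without Hras 3, -0.54 without NSC 1 and -0.38 without NSC 3, and that of the p53 list -0.099 without Hras 1 and -0.073 without NSC 2.

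Interferon response genes had the highest median of any list in the Hras lines, 1.48, with 37 of 38 positive and 2 rises over the list alone (camera adjusted p = 1.01e-06, adjusted p = 0.668 with an estimated correlation). The list's mean was 3.18 above NSC in Hras 3, 1.45 in Hras 2 and 0.09 in Hras 1, and without Hras 3 the call was lost (adjusted p = 0.119, median 0.66), while without Hras 1 the median was 2.23. Ifi35 differed by 3.25 (limma adjusted p = 0.071) and the interferon-induced Usp18 by 3.42 (limma adjusted p = 0.429). Usp18 was at 6.62, 10.18 and 12.2 in Hras 1, 2 and 3, and at 6.59, 6.05 and 6.09 in NSC 1, 2 and 3. The mesenchymal glioma list was shifted up, with a median of 1.04, 33 of 36 positive and 4 rises over the list alone (camera adjusted p = 0.000183, adjusted p = 0.668 with an estimated correlation), a call lost without Hras 3 (0.138) or NSC 1 (0.148), with a median of 1.635 without Hras 1. Its member Spp1, the secreted protein osteopontin, differed by 4.10 (adjusted p = 0.156).

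Weaker upward shifts were called for ERK pathway output (median 0.68), integrins (0.71), collagens and basement membrane (0.59), cytokines and chemokines (0.52), TGF-beta and BMP pathway (0.47) and hypoxia and glycolysis (0.42), with camera adjusted p between 0.00439 and 0.0379 and adjusted p between 0.668 and 0.781 with an estimated correlation, where the median of all genes was 0.16. Over all genes 0 members were called, and adjusted over the list alone 7 integrins rose and 1 fell, 3 collagens and basement membrane genes rose, 3 cytokines rose, 4 TGF-beta and BMP genes rose and 1 fell, and 0 passed in the other lists. The pericyte and fibroblast markers had a median of 0.34, with 18 of 21 positive and 2 rising and 2 falling over the list alone (camera adjusted p = 0.143). Without Hras 3 all of these but the integrins lost the call, at adjusted p of 0.109 to 0.387, and without NSC 1 all but hypoxia did, at 0.148 to 0.695, with ERK output then directed down. Without dim genes ERK output (0.0702), TGF-beta (0.126), cytokines (0.126) and hypoxia (0.119) lost it, and TGF-beta also after quantile normalization (0.0515). With centred arrays the medians were 0.28 for ERK output, 0.32 for integrins, 0.20 for collagens, 0.13 for cytokines, 0.08 for TGF-beta and 0.03 for hypoxia, beside -0.23 for all genes. Removal of NSC 2 ended the call for hypoxia (0.114), removal of NSC 3 that for TGF-beta (0.116), cytokines (0.0551) and hypoxia (0.238), and removal of Hras 2 that for collagens (0.0503) and cytokines (0.0811). The Notch pathway list was called as shifted down although its median was 0.04 and its mean -0.08 (camera adjusted p = 0.0343, adjusted p = 0.668 with an estimated correlation). It lost the call when arrays were centred (0.511), with a median of -0.35 beside -0.23 for all genes, and without Hras 3 (0.293), NSC 2 (0.433) or NSC 3 (0.149). The ERK output median was 0.44 without Hras 2, the cytokine median 0.27 without Hras 3 and 0.33 without NSC 2, and the hypoxia median 0.78 without NSC 1 and 0.28 without NSC 3. The Notch median was -0.175 without Hras 2, -0.042 without Hras 1, -0.026 without NSC 1, 0.113 without NSC 3, 0.125 without Hras 3 and 0.198 without NSC 2.

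Gene by gene, 0 genes were called between Hras lines and NSC with limma. The smallest adjusted p was 0.071, 2481 genes had an unadjusted p under 0.05, of which 2166 were higher in the Hras lines, and limma's treat called 0. The count rose to 76 without NSC 1, 18 without Erbb2 1, 11 without Erbb2 3 and 70 with array weights, and it was 3 without Hras 3 and 1 without Hras 1 or NSC 3.

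In the Erbb2 lines, genes of the ATF4 and unfolded protein response and of sterol synthesis were higher than in NSC as lists, where the median of all genes was -0.14. Of 30 ATF4 and unfolded protein response genes 26 had a positive change, with a median of 0.91 (camera adjusted p = 2.95e-14), and 13 rose when adjusted over the list alone against 0 over all genes. The adjusted p = 0.399 with an estimated correlation. Chac1, which degrades glutathione, was at 10.68 ± 0.63 against 7.95 ± 0.54 (SD, n = 3 each, change 2.73, limma adjusted p = 0.146), and the pseudokinase Trib3 differed by 2.09 (adjusted p = 0.159). Sterol synthesis genes had a median of 0.52, with 21 of 25 positive and 2 rises over the list alone (camera adjusted p = 1.08e-07, adjusted p = 0.709 with an estimated correlation), and Dhcr7, an enzyme of cholesterol synthesis, differed by 1.14 (adjusted p = 0.252). Oligodendrocyte precursor genes had a median of 1.08, with 17 of 23 positive and 2 rises over the list alone (camera adjusted p = 6.4e-06, adjusted p = 0.709 with an estimated correlation), led by Pdgfra at 4.85 (adjusted p = 0.0599). The list's mean against NSC was 1.94 and 1.38 in Erbb2 1 and 2. In Erbb2 3 it was 0.15, within the range of the NSC arrays (-0.20 to 0.165). Cell cycle genes had a median of 0.36, with 37 of 46 positive and 0 called either way (camera adjusted p = 3.88e-06, adjusted p = 0.709 with an estimated correlation), and the mitotic kinase Plk1 differed by 1.10 (adjusted p = 0.27). The cell cycle list's mean against NSC was 0.35, 0.38 and 0.29 in Erbb2 1, 2 and 3. These lay within the range of the NSC arrays, at 0.74, -0.51 and -0.23 in NSC 1, 2 and 3. The cell cycle median was 0.74 without NSC 1, 0.14 without NSC 2 and 0.19 without NSC 3, and the oligodendrocyte precursor median 0.66 without Erbb2 1.

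The list of neural stem cells and radial glia was shifted down in the Erbb2 lines, with 25 of 28 negative, a median of -0.61 and 3 falls over the list alone (camera adjusted p = 0.0028, adjusted p = 0.709 with an estimated correlation), a call lost without NSC 2 (0.235). Egfr differed by -4.18 (adjusted p = 0.0892) and Lfng by -3.14 (adjusted p = 0.153). The interferon list was called as shifted up, with a median of 0.53 (camera adjusted p = 0.00268, adjusted p = 0.789 with an estimated correlation). Its mean was 1.99 above NSC in Erbb2 3 and below NSC in Erbb2 1 and 2, at -0.45 and -0.31, and without Erbb2 3 the adjusted p was 0.977. Its median was 0.96 without Erbb2 1, 0.915 without Erbb2 2, -0.37 without Erbb2 3 and 0.26 without NSC 2. ERK pathway output was shifted up with a median of 0.16 and 22 of 34 positive (camera adjusted p = 0.00489, adjusted p = 0.709 with an estimated correlation), and lost the call after quantile normalization (0.0967) and without Erbb2 3 (0.0507) or NSC 1 (0.641). Its members Spry3 and Phlda1 differed by 2.41 and 2.09 (adjusted p = 0.363 and 0.424). The ERK output median was 0.30 without Erbb2 2, 0.014 without Erbb2 3, 0.039 without NSC 1, 0.26 without NSC 2 and 0.36 without NSC 3.

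Of the other lists called in the Erbb2 lines, matrix proteases and inhibitors (median 0.31, camera adjusted p = 0.00633) lost the call without Erbb2 3 (0.0513) or NSC 1 (0.0522), and myelinating oligodendrocyte genes (median 0.40, camera adjusted p = 0.0165) without Erbb2 2 (0.0576), NSC 1 (0.0522) or NSC 3 (0.0729). Both had an adjusted p = 0.709 with an estimated correlation. The mesenchymal glioma list was called with a median of only 0.004 (camera adjusted p = 0.0199, adjusted p = 0.789 with an estimated correlation). Its median was -0.02 after quantile normalization, and the call was lost after quantile normalization (0.126), without dim genes (0.0887) and without Erbb2 3 (0.283), Hras 3 (0.0523) or NSC 1 (0.328). Blood and choroid plexus genes were shifted down, with a median of -0.33 and Otx2 at -2.41 (camera adjusted p = 0.0165, adjusted p = 0.752 with an estimated correlation), a call lost after quantile normalization (0.183) and without Erbb2 3 (0.085). The protease median was 0.50 without Erbb2 2 and 0.088 without Erbb2 3, the myelinating oligodendrocyte median 0.21 without Erbb2 1 and 0.20 without NSC 3, the choroid plexus median -0.205 without NSC 1, and the mesenchymal median between -0.113 (without Erbb2 3) and 0.271 (without NSC 3). In all, 2 genes were called in Erbb2 lines against NSC with limma: Itga8, which rose by 5.11, from 5.92 ± 0.65 to 11.03 ± 0.51 (SD, n = 3 each, adjusted p = 0.0427), and Lpo, which fell by 2.99 (adjusted p = 0.0427). An unadjusted p under 0.05 was reached by 1909 genes. The count was 0 without Erbb2 1, NSC 1 or NSC 2, 1 without NSC 3, 5 without Erbb2 2, 8 without Hras 1, 10 without Hras 3 and 13 without Erbb2 3.

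The changes of the Hras and the Erbb2 lines against NSC resembled each other, and both rest on the same NSC arrays. Across genes, which are not independent replicates, the correlation of the log2 changes was 0.70, where unchanged groups simulated against shared controls gave 0.50. The covariance was 0.22 against 0.096 in the simulation, a difference of 0.12. With an unadjusted p under 0.05, 754 genes changed in the same direction in both, 556 higher and 198 lower, and 3 in opposite directions. The simulation gave 266, and independent lists of these sizes would share 94.9 higher and 15.3 lower genes. With adjusted p, 0 genes were called in both comparisons. With 3 NSC arrays the controls cannot be divided into parts of 2, so no comparison with separate controls was made.

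Between the 2 tumour groups, the Hras lines had higher cell cycle and lower sterol and stress response expression than the Erbb2 lines as lists, relative to a median of 0.29 over all genes. All 46 cell cycle genes had a positive difference, with a median of 0.85, or 0.56 above that of all genes (camera adjusted p = 9.71e-06, adjusted p = 0.757 with an estimated correlation). Cenpe differed by 1.43 and the kinase Melk by 1.30 (limma adjusted p = 0.391 each). Sterol synthesis genes had a median of -0.21, or -0.51 relative to all genes, with 21 of 25 negative (camera adjusted p = 4.79e-09, adjusted p = 0.516 with an estimated correlation). Insig1, a regulator of sterol synthesis, differed by -0.70 (limma adjusted p = 0.394). It was at 11.95, 10.82 and 11.29 in Hras 1, 2 and 3, and at 12.08, 11.69 and 12.39 in Erbb2 1, 2 and 3. The ATF4 and unfolded protein response list had a median of -0.24, or -0.53 relative to all genes (camera adjusted p = 7.14e-07, adjusted p = 0.516 with an estimated correlation), and Chac1 differed by -1.65 (adjusted p = 0.391). The sterol median was -0.054 without Erbb2 1, -0.35 without Hras 1 and -0.325 without Erbb2 2. The ATF4 and unfolded protein response median was -0.062 without Erbb2 1, -0.136 without Hras 1, -0.375 without Erbb2 3 and 0.027 without Erbb2 2, the last beside 0.27 for all genes. In these 3 lists, which kept their camera call under all 13 settings, 0 genes were called either over all genes or over the list alone. The array means of the sterol and the ATF4 list overlapped between the groups. Against NSC the sterol mean was 0.50, 0.13 and 0.27 in Hras 1, 2 and 3, and 0.84, 0.28 and 0.38 in Erbb2 1, 2 and 3. The ATF4 list's mean was 0.44, 0.64 and 0.89 in the Hras lines and 1.04, 1.085 and 0.45 in the Erbb2 lines.

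Collagens and basement membrane genes were shifted up in Hras against Erbb2 lines, with 33 of 36 positive, a median of 0.64 and 1 rise over the list alone (camera adjusted p = 0.00117, adjusted p = 0.757 with an estimated correlation), a call lost without Erbb2 2 (0.0654). The median was 0.29 after quantile normalization and 0.22 with centred arrays, beside -0.007 and -0.127 for all genes, and the pericyte and fibroblast markers had a median of 0.54, with 20 of 21 positive. Hypoxia and glycolysis genes were shifted up, with a median of 0.73 and 29 of 32 positive (camera adjusted p = 0.00655, adjusted p = 0.757 with an estimated correlation), a call lost without Erbb2 2 (0.112) or Hras 3 (0.178). The basement membrane protein Nid1 differed by 2.27 and the carbonic anhydrase Car9 by 2.39 (limma adjusted p = 0.391 each). Nid1 was at 6.71, 8.77 and 10.35 in Hras 1, 2 and 3, and at 5.92, 5.16 and 7.93 in Erbb2 1, 2 and 3. Car9 was at 7.52, 5.63 and 10.03 in the Hras lines and at 5.96, 5.01 and 5.02 in the Erbb2 lines. Nid1 in Erbb2 2 and Car9 in Erbb2 2 and 3 lay below the dim limit of 5.31. Oligodendrocyte precursor genes were shifted down, with a median of -0.35, or -0.645 relative to all genes (camera adjusted p = 1.68e-06, adjusted p = 0.757 with an estimated correlation), a call lost without Hras 3 (0.366) and when arrays were centred (0.0822), where the median was -0.77. It was 0.037 without Erbb2 1, -0.77 without Hras 1, -0.55 without Hras 2, -0.70 without Erbb2 3 and 0.305 without Hras 3. Their mean against NSC was 1.94, 1.38 and 0.15 in Erbb2 1, 2 and 3, and 1.93, 1.06 and -0.67 in Hras 1, 2 and 3, so lines of both oncogenes lay at either end. Astrocyte genes were shifted down with a median of -0.21, or -0.50 relative to all genes (camera adjusted p = 0.000184, adjusted p = 0.516 with an estimated correlation), a call lost when arrays were centred (0.171), where the median was -0.625. It was -0.49 without Erbb2 1, -0.072 without Hras 1, 0.135 without Erbb2 2 and -0.34 without Hras 2.

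No gene passed the test between Hras and Erbb2 lines. With limma 0 genes were called, the smallest adjusted p was 0.391, 2625 genes had an unadjusted p under 0.05, and limma's treat and each of the other settings called 0 as well. The 3 Hras arrays lay entirely above or below the 3 Erbb2 arrays for 5725 genes (27.7%), where chance gives 10% and the median of all genes was 0.29. Pearson correlations between arrays over genes averaged 0.941 for tumour lines of the same oncogene and 0.940 for lines of different oncogenes (one-sided exact permutation p = 0.3 over 10 splits, where the smallest possible p is 0.1). The highest correlation of any pair of arrays, 0.972, was that of Hras 1 and Erbb2 2. Dnm2, the gene floxed in the strain of NSC 3, had a level of 9.99 there against 8.82 and 10.16 in NSC 1 and 2 and was not called in any comparison.

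Sex-linked transcripts varied between the lines. Xist, transcribed from the inactive X chromosome, was at 3.97 in Erbb2 1 and Erbb2 3 and at 8.83 to 10.23 in Erbb2 2 and the Hras lines, while the mean of the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty was 7.02 and 8.18 in Erbb2 1 and 3 and 4.03 to 4.61 in the others. NSC 1 and NSC 3 had both, with Xist at 7.08 and 7.09 and a Y-linked mean of 8.25 and 8.24, and NSC 2 had Xist at 10.39 and a Y-linked mean of 5.55. The list was shifted down in Hras lines against NSC (median -2.58, camera adjusted p = 4.8e-05, adjusted p = 0.314 with an estimated correlation), and 4 of 5 members fell when adjusted over the list alone.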

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

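The tests of array scale, of the NSC 3 strain, of fibroblasts and of the sex of the animals were chosen after the results had been seen, and the counts of other splits and the test of the cell cycle list were planned.

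The mean of both tumour groups had large changes against NSC, 73 genes with a median absolute change of 2.18 log2 units. Array medians ran from 6.56 to 7.19, too narrow a range for shifts between arrays to give changes of that size. After quantile normalization the median change of the called genes was 2.215, and 12 kept the call. The strain of NSC 3 cannot be judged, since all 73 genes, called with that array, also had NSC 1 and 2 apart from every tumour array. Without NSC 3 their median change was 2.28, and 13 kept the call. The values argue against fibroblasts that express 7 abundant genes, whose median change was 0.0061 and highest 0.43. Of these, Acta2 was at -2.27 (limma adjusted p = 0.0655), and Dcn and Lum lay below the dim limit of 5.31. Fibroblasts or pericytes without these transcripts stay open. Of 21 markers 16 were positive, 2 rose and 2 fell over the list alone, and Prrx1 rose by 2.82. Rises were 72.6% of the calls as deposited and 16.67% of the fewer calls after quantile normalization, so whether scale gave the excess of rises stays open. All 73 genes kept their direction there. That cannot decide the question, since they were called in these data with changes of at least 1.17 log2 units. The median residual SD of the called genes was 0.495 as deposited and 0.504 after quantile normalization. The 9 arrays have 84 splits into 6 and 3, each tested in a fit of 2 groups. Of these, 3 (the real one included) gave at least the real split's 82 genes, a share under 0.05. The highest other split gave 204, with Erbb2 1, Hras 1 and Erbb2 2 set against the rest. That count points to a structure of the samples besides the groups. With such a structure the arrays are not interchangeable, so the share cannot exclude chance. The oncogenes themselves, passage and the different reporters of the NSC arrays stay open and were not tested, and if the leading numbers of the descriptions (1 to 3 for tumour arrays, 4, 4 and 5 for NSC) mark batches, batch and group cannot be told apart.

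The sex-linked list had a median of -2.24 between Hras and Erbb2 lines (camera adjusted p = 0.000184, adjusted p = 0.516 with an estimated correlation), a call lost when arrays were centred (0.0937), where the median was -2.66. It was -3.41 without Erbb2 2 and -1.39 without Erbb2 3. In 6 of 6 tumour arrays either Xist was at log2 7 or above or the Y-linked mean was at 6 or above, and not both, which is consistent with lines from animals of either sex. The same held for 1 of 3 NSC arrays, and NSC 1 and NSC 3 carried both signals. Cultures pooled from animals of both sexes are a possible explanation for these NSC arrays that was not tested. NSC 2 met the rule with a Y-linked mean of 5.55, above the 4.03 to 4.61 of the tumour arrays with Xist. Whether NSC 2 also carried a low Y-linked signal stays open.

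Cell cycle genes were higher in the Hras lines than in NSC, with a median of 1.17 (adjusted p = 0.32 with an estimated correlation). They differed between Hras and Erbb2 lines by a median of 0.849 beside 0.29 for all genes (adjusted p = 0.757 with an estimated correlation). With centred arrays that median was 0.43 beside -0.127 for all genes. A single NSC array with low expression is argued against for the first, since the lowest median without any NSC array was 0.899, that without NSC 2. The difference in growth rate that the oncogenes could cause was not tested and stays open.

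The other lists called between Hras and Erbb2 lines are given as values beside the median of 0.29 over all genes. Sterol synthesis had a median of -0.213, and the ATF4 and unfolded protein response -0.235, both with an adjusted p = 0.516 with an estimated correlation. The ATF4 median was 0.027 without Erbb2 2. The astrocyte list had -0.207 (adjusted p = 0.516 with an estimated correlation), a call lost with centred arrays (0.171), and 0.135 without Erbb2 2. The oligodendrocyte precursor list had -0.352 (adjusted p = 0.757 with an estimated correlation), a call lost with centred arrays (0.0822) and without Hras 3 (0.366), where the median was 0.305, and 0.037 without Erbb2 1. Collagens and basement membrane had 0.636, a call lost without Erbb2 2 (0.0654), and hypoxia and glycolysis 0.732, a call lost without Erbb2 2 (0.112) or Hras 3 (0.178), both with an adjusted p = 0.757 with an estimated correlation. Interferon response had 1.16 (camera adjusted p = 0.043, adjusted p = 0.905 with an estimated correlation), a call lost without Erbb2 1 (0.851), Erbb2 2 (0.431), Hras 3 (0.423, directed down), NSC 1 (0.247), NSC 2 (0.0989) or NSC 3 (0.0568), and without dim genes (0.0501), with a median of 1.82 without Hras 1, 0.745 without Erbb2 2, 1.88 without Erbb2 3 and 0.38 without Hras 3. Myelinating oligodendrocyte genes had 0.03 with a camera test directed down (adjusted p = 0.043, adjusted p = 0.757 with an estimated correlation), a call lost without Erbb2 1 (0.183), Erbb2 2 (0.162), Hras 3 (0.469) or NSC 1 (0.0532), and with centred arrays (0.255), with a median between -0.054 (without Erbb2 3) and 0.198 (without Hras 3). Endothelium markers had 0.434 (camera adjusted p = 0.0486, adjusted p = 0.845 with an estimated correlation), a call lost without Erbb2 2 (0.102), Hras 2 (0.137), Erbb2 3 (0.172), Hras 3 (0.246), NSC 1 (0.0632), NSC 2 (0.0575) or NSC 3 (0.0568), and after quantile normalization (0.278), where the median was 0.005. Pericyte and fibroblast markers had 0.537 (camera adjusted p = 0.0401, adjusted p = 0.757 with an estimated correlation), a call lost without Erbb2 1 (0.085), Erbb2 2 (0.205), Hras 3 (0.2), NSC 1 (0.0632) or NSC 2 (0.0544), without dim genes (0.0772) and after quantile normalization (0.126), where the median was 0.1.

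For the pairwise gene counts, 6 arrays make 10 splits, too few for a share under 0.05. For Hras against NSC 10 of 10 splits gave at least the real count of 0, with a highest other count of 0. For Erbb2 against NSC 1 of 10 did, with a real count of 2 and a highest other count of 0. For Hras against Erbb2 10 of 10 did, with a real count of 0 and a highest other count of 346, which came from Erbb2 1, Hras 1 and Erbb2 2 set against Hras 2, Erbb2 3 and Hras 3 and points to a structure of the samples.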

How the results depend on the processing

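The list tests of the mean of both tumour groups, with their alternatives, were chosen after the pairwise counts had been seen. Of 612 alternative values for 34 called gene results, 322 kept direction and call, 290 kept the direction and lost the call, and 0 reversed. Of 2454 for 135 uncalled gene results, 2384 stayed uncalled in the same direction, 48 passed the threshold and 22 reversed. The mean of several rows of a symbol was not run, since each symbol has 1 row. No detection call was available, so expression near background cannot be told from absence. Except where fewer arrays or a stricter threshold is the alternative itself, the cause was not tested.

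The count for Hras minus NSC, 0, was 2 after quantile normalization, 1 with centred arrays, 20 with only the groups compared, 70 with array weights, 9 with the title number as a replicate block, and 0 to 76 without an array. That for Erbb2 minus NSC, 2, was 1 after quantile normalization, 8 without dim genes, 8 with only the groups compared, 18 with a trended robust variance, 37 with weights, 27 with the block, 0 at an adjusted p under 0.01, 0 with treat, and 0 to 13 without an array. That for the mean of both groups, 73, was 12 after quantile normalization, 23 with centred arrays, 92 with the block, 0 at an adjusted p under 0.01, 2 with treat, and 0 to 70 without an array. That for Hras minus Erbb2 was 0 in all. Genes called the same way in both groups, 0, were 1 after quantile normalization, 1 with centred arrays, 1 with only the groups compared, 21 with weights, 9 with the block and 0 to 6 without an array. Of the 9 arrays 4 correlated best with an array of their own number, a count that does not settle whether the title numbers pair the arrays.

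Lists called were 0 in each of the 4 comparisons with an estimated correlation and 0 with the directional form of fry. Its mixed form did call lists against NSC. For the mean of both tumour groups its adjusted p was 1.93e-06 for Hox and positional homeobox genes, 4.96e-05 for matrix proteases and 9.73e-05 for integrins. Other lists were not called by it, such as interferon response (0.216) and mesenchymal glioma (0.191). Between Hras and Erbb2 lines its smallest adjusted p was 0.104. Without an array the lists called by camera were 8 to 16 for Hras minus NSC (15), 6 to 15 for Erbb2 minus NSC (12), 7 to 14 for Hras minus Erbb2 (12) and 12 to 18 for the mean (16).

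Reversed log2 differences were all uncalled. For Hras minus NSC, Etv5 was -0.107 after quantile normalization, -0.283 with centred arrays, -0.404 with weights, and -0.476 (without NSC 1) to 0.442 without an array, and Hras1 was -0.067 after quantile normalization and -0.22 with centred arrays. For Erbb2 minus NSC, Etv5 was -0.094 (without NSC 1) to 0.825. For the mean, Etv5 was -0.195 with weights and -0.285 (without NSC 1) to 0.633, and Hras1 was 0.141 with weights and -0.21 to 0.217 (without NSC 1). For Hras minus Erbb2 without an array, Slc7a11 was -1.896 to 0.201 (without Hras 1), Cntn1 -3.398 to 0.405 and Lhfpl3 -2.459 to 0.18 (both without Hras 3), Etv4 -0.422 to 0.157 (without Erbb2 1), Erbb2 -0.778 to 0.309 (without Erbb2 3) and Dnm2 -0.256 to 0.208 (without Hras 1).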

Other observations

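Tumour lines of either oncogene differed widely in the levels of Erbb3 and Usp18. The genes in this paragraph were chosen after their values were seen, and no test was run between lines. Erbb3, a partner receptor of Erbb2, had log2 levels of 11.36, 11.03 and 9.94 in Erbb2 1, Hras 1 and Erbb2 2, 8.49 in Hras 2, and 4.96 and 5.99 in Erbb2 3 and Hras 3, beside 6.06, 5.10 and 5.0 in NSC 1, 2 and 3. The interferon-induced Usp18 had 5.48, 6.62 and 6.3 in Erbb2 1, Hras 1 and Erbb2 2, 10.18 in Hras 2, and 10.73 and 12.2 in Erbb2 3 and Hras 3, beside 6.59, 6.05 and 6.09 in the NSC arrays.

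Further lists were called in the mean of both tumour groups against NSC. Ets factors other than the PEA3 group had a median of 0.33 with 15 of 23 positive and 0 members called over all genes or adjusted over the list alone (camera adjusted p = 0.0378, adjusted p = 0.564 with an estimated correlation). That call was lost with centred arrays (0.0517), without dim genes (0.104) and without Hras 2 (0.0752), Erbb2 3 (0.0576), NSC 1 (0.423) or NSC 3 (0.0627), and the median was 0.21 without NSC 1. ERK pathway output had a median of 0.41 (camera adjusted p = 0.00314) and the mesenchymal glioma list 0.59 (0.000692), both with an adjusted p = 0.564 with an estimated correlation, and both lost the call without NSC 1, at 0.993 and 0.178. The ERK median was 0.25 without NSC 1 and the mesenchymal median 0.32 without Hras 3. Of 47 Hox and positional homeobox genes 3 rose and 3 fell when adjusted over the list alone and only Otx2 fell over all genes, with a median of 0.03 and no shift of the list (camera adjusted p = 0.955).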
